A study of Mus musculus and Homo sapiens with 28 samples.

How the data were processed

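Germ cells were taken from fetal testes of genotyped mouse fetuses of a 129 background on 3 days (E12.5, E13.5, E14.5), wild type or homozygous for the Ter mutation of Dnd1, and sorted for a GFP reporter driven by Oct4. Per the labels, total RNA was extracted with a column kit for small samples, and libraries were made by Smart-seq2, which amplifies full-length complementary DNA from little RNA, with Nextera XT. That amplification raises the noise of rare transcripts and carries no molecular barcodes. Each of the 6 groups of genotype and age has 4 libraries, called biological replicates. Whether they come from separate fetuses or litters is not given in the sources used here, so p-values measure only the spread between these samples.

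The deposited mouse table gives RPKM per gene and library, made by the authors, for 23941 genes with mm9 coordinates. The submitters' processing notes list Bowtie2 2.2.4, Cufflinks 2.2.0 and Cuffdiff 2.2.0 with mm9, with no role or order. The read counts, the sequencing depth, the handling of reads that map to several genes and any scaling between libraries are not given in the sources used here. The sums of RPKM differed between libraries, from 728811 to 976991, so the values do not add to 1 fixed sum. Low values showed no steps of whole reads, so depth could not be recovered and counting error could not be set against the spread between libraries. Between 10433 and 12057 genes reached 1 RPKM in a library, and the 10 most abundant genes took 6.59% to 13.4% of the sum. Mitochondrial transcripts, 1 of the 37 gene lists, are not in the table.

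The binding experiment used HEK293 cells transfected with FLAG-tagged DND1, with RNA digested to fragments, immunoprecipitated and sequenced with molecular barcodes (2 RIP and 2 input libraries). The submitters' processing notes list TopHat2 and hg19. Per the file headers, the deposited table gives the number of binding sites per gene found in either replicate and the number identical in both, those in 3' untranslated regions and those with the DAUBAW motif, and a yes or no for expression in HEK293. These are counts of called sites, not reads. The site caller, its threshold, the use of the input and of the barcodes, and the rule for expression are not given in the sources used here. Of 31686 entries, 27 whose names had turned into dates were left out. The cells also included an untagged control per the labels, which is not analysed here.

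Values were analysed as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3: 6 group means, empirical Bayes with trend and robust options, and Benjamini-Hochberg adjustment over the 12669 genes with at least 1 RPKM in at least 4 samples, with a threshold of adjusted p under 0.05. Contrasts were the mutant against wild type at each age, the differences of that effect between ages, and the steps with age in each genotype. The model, the filter, the gene lists, the contrasts, the alternatives and the rule for named genes were fixed before the data were examined. The design then had 24 separate samples. After the replicates were compared, mutant E12.5 libraries 1 and 4 were averaged and counted as 1 sample, so that 23 samples entered the fit, a departure chosen on the data. With the 24 libraries 12752 genes were tested. Shared missing values of that pair fell outside the range of every other pair, but the noise of read sampling could not be tested without counts.

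Each list was tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, and adjusted over the lists of 1 contrast. Lists can share genes, so the tests of lists are not independent. Members were counted with p adjusted over all genes and adjusted over the list alone. Genes were named by rule: Dnd1, then at each age the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 RPKM in the higher group and no overlap between the genotypes, leaving out predicted loci, then up to 4 members of each list described, called members with the smallest adjusted p first. For other contrasts 4 genes per direction were named by the same limits, and for binding the 10 genes with the most shared sites. Dnd1 was also tested with an exact permutation test, two-sided.

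Genes with at least 1 shared site were set against the other genes expressed in HEK293 by camera, by Fisher's exact test in each direction, and by the median against 10000 random lists matched on expression. Human and mouse genes were matched by the same symbol. The wild type step and the mutant effect were correlated across genes, with the wild type libraries of the later age divided between both sides, and the undivided value was set beside 100 simulations with no effect. The pipeline was tested on simulated data with 200 changed genes per comparison: 4-fold changes were recovered in 97%, 98.5% and 92.4% of genes over the 3 ages, 2-fold changes in 70.1%, 59.7% and 65.7%, and 1.5-fold changes in 17.9%, 31.3% and 17.9%.

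Alternatives were a pseudocount of 0.1, no filter, libraries rescaled to a sum of 1000000, quantile normalization, array weights, no trend and robust options, only the groups compared, each replicate left out in turn, the replicate number as a block (with the 24 libraries counted separately), at least 2 shared sites, genes with the most sites and other halvings of the wild type libraries. The 24 libraries counted separately, the design fixed first, became an alternative once libraries 1 and 4 were averaged. Added after the data were seen were the fits without mutant E12.5 libraries 1 and 4 and without 3 libraries that stood apart (mutant E14.5 library 2 and mutant E13.5 libraries 2 and 4), the Sertoli score (mean log2 level of the Sertoli list) as a covariate, sites of either replicate and the test of lists among genes with sites. A count was taken as moved when it changed by more than 1.5 times. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.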

Results

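Male germ cells of the mouse fetal testis were profiled by RNA sequencing on embryonic days E12.5, E13.5 and E14.5, the days on which these cells leave the mitotic cycle and begin male differentiation. Wild type fetuses were compared with fetuses homozygous for Ter, a point mutation that places a premature stop codon in Dnd1, the gene of a germ cell RNA-binding protein. Both genotypes carried a GFP reporter driven by Oct4, a transcription factor of pluripotent and early germ cells, by which the cells were sorted. Each genotype and age has 4 libraries, 24 in all. Mutant E12.5 libraries 1 and 4 lay closer to each other than any other pair within a group and were counted as 1 sample, so that n = 3 for mutant E12.5 and n = 4 for the other 5 groups. Values are RPKM with SD, fold changes are on the log2(RPKM + 1) scale with SE, and this scale understates changes of genes with low values.

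Dnd1 transcript (chromosome 18, 36919893 to 36925868, mm9) was present in every library. At E12.5 it stood at 146 ± 21 RPKM in the mutant and 166 ± 49.3 RPKM in wild type, a difference within the spread between replicates (log2 fold change -0.15 ± 0.18, limma adjusted p = 0.613; two-sided exact permutation p = 0.657). At E13.5 it was 2.12-fold lower in the mutant (98.1 ± 12.7 against 209 ± 24.4 RPKM; log2 fold change -1.09 ± 0.17, adjusted p = 9.16e-05), and at E14.5 it was 4.21-fold lower (88.2 ± 12.1 against 377 ± 69.2 RPKM; -2.07 ± 0.17, adjusted p = 4.5e-09). At both later ages all 4 mutant libraries lay below all 4 wild type libraries (exact permutation p = 0.0286, the smallest that 4 against 4 allows). Mutant libraries at E12.5 held 172, 129, 140 and 167 RPKM, at E13.5 106, 83.8, 111 and 91.2, and at E14.5 95.5, 70.8, 97.4 and 88.9 RPKM. Wild type libraries held 236, 164, 124 and 142 RPKM at E12.5, 178, 233, 202 and 223 at E13.5, and 442, 279, 396 and 390 at E14.5.

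**Figure D1:**
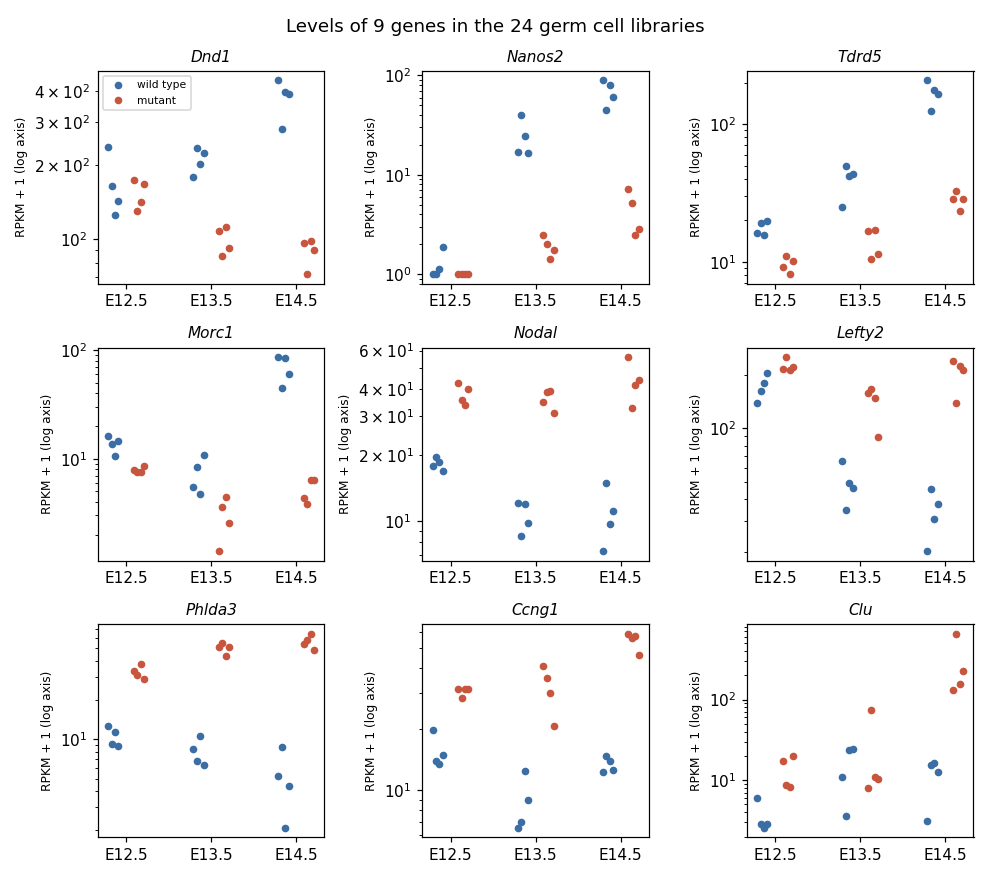
Levels of 9 genes in each of the 24 libraries (RPKM + 1, logarithmic axis), by age and genotype. Each point is 1 library. Dnd1 is the mutated gene. Nanos2, Tdrd5 and Morc1 belong to male germ cell differentiation, Nodal and Lefty2 to Nodal signalling, Phlda3 and Ccng1 to the p53 targets and Clu to the Sertoli cell markers.

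At E12.5 mutant germ cells already held less of several germ cell transcripts. Uchl1, a deubiquitinase abundant in germ cells and neurons (chromosome 5, 67017734 to 67078473), fell from 104 ± 25.7 RPKM in wild type to 11.1 ± 0.863 RPKM in the mutant (log2 fold change -3.08 ± 0.23, adjusted p = 1.69e-08). Asz1, a germ cell protein needed for piRNA production (chromosome 6, 18000964 to 18059061), fell from 80.2 ± 8.66 to 11.1 ± 1.81 RPKM (-2.75 ± 0.23, adjusted p = 4.76e-08). The small heat shock gene Hspb1 (chromosome 5, 136363789 to 136365433) rose from 8.75 ± 5.4 to 87.4 ± 18.7 RPKM (3.29 ± 0.34), and Cldn3, a tight junction component (chromosome 5, 135462084 to 135477220), from 1.65 ± 0.806 to 24.2 ± 6.43 RPKM (3.28 ± 0.36). The next largest falls were those of Hemt1, Cox7b2, Dab1 and Gml (log2 fold change -2.94, -2.88, -2.44 and -2.41), and the next largest rises those of Mt1, Cldn6, Aard and Cd164l2 (3.08, 2.83, 2.70 and 2.64). Aard belongs to the fixed list of Sertoli cell genes.

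Gene groups fixed before the data were examined moved too, given by the median log2 fold change of members. Of 24 tested p53 targets, which restrain the cell cycle or promote cell death, 11 rose and 0 fell (15 and 0 adjusted over the list alone). The p53 list had a median of 0.61 (adjusted p = 8.54e-07, and adjusted p = 0.101 with an estimated correlation). Among them were Phlda3 (1.67 ± 0.29), Btg2 (1.48 ± 0.29) and Ccng1 (0.99 ± 0.21). Of 19 genes of the piRNA pathway, which silences transposons, 9 fell and 0 rose (11 and 1 adjusted over the list alone), Asz1, Mov10l1 (-1.57 ± 0.22) and Tdrkh (-1.24 ± 0.19) among them. The piRNA list had a median of -0.88 (adjusted p = 1.31e-06, and adjusted p = 0.201 with an estimated correlation). Of 25 germline genes known to be silenced by promoter methylation 10 fell and 0 rose (15 and 2 adjusted over the list alone), with Slc25a31 at -2.16 ± 0.27. The methylation-sensitive germline list had a median of -0.76 (adjusted p = 2.03e-06, and adjusted p = 0.177 with an estimated correlation). Of 38 oxidative phosphorylation genes 10 fell and 0 rose (18 and 0 adjusted over the list alone), each by less than 2-fold in the 4 examples Ndufv1 (-0.62), Uqcrc2 (-0.72), Cycs (-0.60) and Ndufa5 (-0.63). The oxidative phosphorylation list had a median of -0.31 (adjusted p = 5.69e-07, and adjusted p = 0.218 with an estimated correlation). Meiotic entry genes fell in 8 of 23 members and rose in 0 (11 and 0 adjusted over the list alone), with Sycp3 at -1.47 ± 0.25. The meiotic entry list had a median of -0.73 (adjusted p = 0.000132, and adjusted p = 0.177 with an estimated correlation). Naive and shared pluripotency genes rose in 7 of 29 members and fell in 0 (8 and 0 adjusted over the list alone), with Nodal at 1.02 ± 0.20 and Dppa5a at 0.58 ± 0.14. The naive and shared pluripotency list had a median of 0.36 (adjusted p = 0.00153, and adjusted p = 0.289 with an estimated correlation). Cell cycle arrest genes rose in 6 of 25 and fell in 0 (6 and 0 adjusted over the list alone), including Trp53, the gene of p53 (0.72 ± 0.16), and Cdkn1a (0.73 ± 0.16). The cell cycle arrest list had a median of 0.40 (adjusted p = 0.000933, and adjusted p = 0.101 with an estimated correlation). Markers of other cells of the testis stood beside these groups. Of 25 Sertoli cell genes 2 rose and 1 fell (the same adjusted over the list alone), with a median of 1.02 (adjusted p = 0.00574, and adjusted p = 0.678 with an estimated correlation). Of 11 leukocyte genes 2 rose and 0 fell (the same adjusted over the list alone), with a median of 0.63 (adjusted p = 0.012, and adjusted p = 0.474 with an estimated correlation). Of 12 endothelial genes 1 rose and 0 fell (the same adjusted over the list alone), with a median of 0.32 (adjusted p = 0.0288, and adjusted p = 0.161 with an estimated correlation). These markers were uneven between mutant libraries: the mean log2 level of the Sertoli list was 2.61 and 2.58 in libraries 1 and 4, 2.03 in library 3 and 0.82 in library 2, and that of the leukocyte list 1.41, 1.48, 1.03 and 0.43 in the same order. Without libraries 1 and 4, a setting chosen after the data were seen, the Sertoli, leukocyte and endothelial lists lost their calls (adjusted p = 0.175, 0.269 and 0.109).

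In all, 1776 of 12669 tested genes passed the threshold of limma at E12.5, 713 higher and 1063 lower in the mutant, 286 and 206 of them by at least 2-fold. With the 24 libraries counted separately, as the design first had it, 2535 passed, and without mutant libraries 1 and 4 altogether 1204. The count fell to 1008 without wild type library 4 and 1089 without wild type library 3, and 51.3% of the called genes were higher, in place of 40.1%, when libraries were rescaled to equal sums.

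At E13.5 the mutant cells lacked most of the transcript of Nanos2, an RNA-binding protein that promotes the male germ cell fate (chromosome 7, 19572873 to 19574311). It stood at 0.908 ± 0.432 RPKM against 23.5 ± 10.7 RPKM in wild type (log2 fold change -3.62 ± 0.32, adjusted p = 9.77e-08). Egr4, a zinc finger transcription factor (chromosome 6, 85461116 to 85463536), stood at 1.13 ± 1.86 against 47.8 ± 29.1 RPKM (-4.64 ± 0.56, adjusted p = 1.85e-05), and Bcl11a, a transcriptional repressor (chromosome 11, 23978056 to 24073558), at 1.02 ± 0.776 against 10.9 ± 0.69 RPKM (-2.63 ± 0.24). Rhox6 and Rhox9, neighbouring homeobox genes of the X chromosome (35180232 to 35183034 and 35252274 to 35254947), were higher in the mutant, at 153 ± 19.6 against 15.3 ± 14.6 RPKM (3.64 ± 0.51) and 228 ± 41.5 against 30.8 ± 24.4 RPKM (3.13 ± 0.47). Both belong to a cluster of similar genes that can share reads. Ak1, an adenylate kinase (chromosome 2, 32477278 to 32490578), rose from 9.57 ± 8.28 to 82.7 ± 13.4 RPKM (3.24 ± 0.37). Other large changes were those of Gal, Krt17 and Fbxo41 (-3.05, -3.04 and -2.72) and of Tff2, Mogat2 and Dcxr (3.58, 3.39 and 3.22).

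The p53 targets rose again, in 14 of 24 members with 0 falling (18 and 0 adjusted over the list alone). The p53 list had a median of 0.74 (adjusted p = 5.08e-12, and adjusted p = 0.00745 with an estimated correlation). Phlda3 (chromosome 1, 137662662 to 137665711) reached 49 ± 4.75 RPKM against 7 ± 1.91 in wild type (2.67 ± 0.27), Ccng1 (chromosome 11, 40562054 to 40568788) 30.9 ± 8.7 against 7.75 ± 2.71 RPKM (1.87 ± 0.20), and Bbc3, which promotes apoptosis, had a log2 fold change of 1.87 ± 0.24. Naive and shared pluripotency genes rose in 9 of 29 members and fell in 1 (12 and 1 adjusted over the list alone), with Nodal at 1.78 ± 0.18, its inhibitor Lefty2 at 1.53 ± 0.24 and Nanog at 0.99 ± 0.16. The naive and shared pluripotency list had a median of 0.37 (adjusted p = 0.000349, and adjusted p = 0.347 with an estimated correlation). Cell cycle arrest genes rose in 8 of 25 and fell in 1 (the same adjusted over the list alone), and apoptosis genes rose in 7 of 26 and fell in 1 (7 and 2 adjusted over the list alone). The cell cycle arrest list had a median of 0.49 (adjusted p = 0.00425, and adjusted p = 0.13 with an estimated correlation). The apoptosis list had a median of 0.18 (adjusted p = 0.0461, and adjusted p = 0.13 with an estimated correlation). Male germ cell differentiation genes fell in 8 of 24 members and rose in 1, Nodal (9 and 2 adjusted over the list alone), and piRNA pathway genes fell in 6 of 19 and rose in 0 (7 and 0 adjusted over the list alone), Asz1 (-1.82 ± 0.21) and Tdrd5 (-1.51 ± 0.20) in both. The male differentiation list had a median of -0.59 (adjusted p = 0.000546, and adjusted p = 0.435 with an estimated correlation). The piRNA list had a median of -0.43 (adjusted p = 0.000342, and adjusted p = 0.435 with an estimated correlation). The germline genes silenced by promoter methylation moved both ways, 7 lower and 3 higher of 25 (9 and 3 adjusted over the list alone), with Brdt at -1.92 ± 0.28 and Rhox6 and Rhox9 among the 3 that rose. The methylation-sensitive germline list had a median of -0.35 (adjusted p = 0.00157, and adjusted p = 0.435 with an estimated correlation). Of 12 endothelial genes 5 rose and 0 fell (the same adjusted over the list alone), including Cldn5 (1.48 ± 0.22), Mmrn2 (1.45 ± 0.21) and Eng (2.14 ± 0.31). The endothelial list had a median of 0.57 (adjusted p = 0.00854, and adjusted p = 0.0739 with an estimated correlation). The Sertoli cell list did not pass (median 0.38, 1 higher and 1 lower of 25, adjusted p = 0.283), but mutant library 2 had a mean log2 level of 3.67 over that list where the other 3 libraries had 1.48 to 1.85.

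At E13.5 1607 genes passed, 954 higher and 653 lower, 405 and 196 of them by at least 2-fold, and 1061 passed without wild type library 2. The share of called genes that were higher was 59.4%, and 48.4% with quantile normalization.

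At E14.5 the most genes were called in the main fit. With the Sertoli score as a covariate the E14.5 count, given below, was lower. That covariate also raised the SE, as given below for the male germ cell differentiation genes, so a lower count need not mean smaller effects. Counts of the earlier ages with that covariate are not given here, so the ages are not compared under it. Nanos2 stood at 3.44 ± 2.22 RPKM in the mutant against 67.9 ± 19.7 in wild type (log2 fold change -4.05 ± 0.32, adjusted p = 3.4e-09), Egr4 at 5.31 ± 3.53 against 136 ± 38.7 RPKM (-4.61 ± 0.56), and Morc1, which represses transposons in the male germ line (chromosome 16, 48431350 to 48631018), at 4.21 ± 1.33 against 67.8 ± 19.9 RPKM (-3.71 ± 0.30). Rrad, a small GTPase (chromosome 8, 107151966 to 107155221), the keratin Krt17 (chromosome 11, 100117531 to 100122303) and the uridine phosphorylase Upp1 (chromosome 11, 9018011 to 9036173) fell as well (-4.53, -4.01 and -3.82). The largest rise was that of Clu, a secreted chaperone abundant in Sertoli cells (chromosome 14, 66587320 to 66600382), at 289 ± 242 RPKM against 10.8 ± 6.01 (4.55 ± 0.77, adjusted p = 0.000185). Amh and Inha, which encode Sertoli cell hormones (chromosome 10, 80267993 to 80270393, and chromosome 1, 75503652 to 75506929), stood at 98.4 ± 83.1 against 3.96 ± 2.3 RPKM and 47.4 ± 38.6 against 1.39 ± 1.06 RPKM. Mutant library 2 held the most of Clu, Amh and Inha (647, 213 and 100 RPKM), and without it their mutant means were 170, 60 and 29.8 RPKM and all 3 were still called (log2 fold change 4.06, 3.49 and 3.57).

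Male germ cell differentiation genes fell in 18 of 24 members and rose in 2 (19 and 2 adjusted over the list alone), and piRNA pathway genes fell in 16 of 19 and rose in 0 (18 and 0 adjusted over the list alone). The male differentiation list had a median of -1.35 (adjusted p = 4.63e-08, and adjusted p = 0.104 with an estimated correlation). The piRNA list had a median of -1.10 (adjusted p = 3.21e-09, and adjusted p = 0.104 with an estimated correlation). Tdrd5, a Tudor domain protein of spermatogenesis (chromosome 1, 158185426 to 158233737), stood at 27.1 ± 3.76 against 168 ± 34.4 RPKM (-2.57 ± 0.20), Asz1 at 23.5 ± 8.42 against 139 ± 31.6 RPKM (-2.56 ± 0.21), and the Piwi protein gene Piwil4 had a log2 fold change of -2.35 ± 0.29. The methylation-sensitive germline genes fell in 15 of 25 and rose in 4 (19 and 4 adjusted over the list alone), and genes of general germ cell identity fell in 10 of 22 and rose in 3 (14 and 3 adjusted over the list alone), with Nanos3 at -2.13 ± 0.20 and Brdt (chromosome 5, 107760213 to 107816077) at -2.88 ± 0.28. The methylation-sensitive germline list had a median of -0.92 (adjusted p = 0.000605, and adjusted p = 0.266 with an estimated correlation). The germ cell identity list had a median of -0.53 (adjusted p = 0.00583, and adjusted p = 0.262 with an estimated correlation). The p53 targets rose in 15 of 24 and fell in 1 (17 and 1 adjusted over the list alone), with Phlda3 at 55.1 ± 6.65 against 4.12 ± 2.78 RPKM (3.62 ± 0.27) and Bbc3 at 2.63 ± 0.24. The p53 list had a median of 0.73 (adjusted p = 3.32e-07, and adjusted p = 0.0498 with an estimated correlation). Trp53 itself (chromosome 11, 69393861 to 69405375) stood at 327 ± 34.8 against 125 ± 30.4 RPKM (1.40 ± 0.15). Cell cycle arrest genes rose in 13 of 25 and fell in 2 (14 and 3 adjusted over the list alone), while proliferation genes rose in 16 of 35 and fell in 2 (the same adjusted over the list alone), so that the inhibitor Cdkn1a (1.52 ± 0.15) and the mitotic kinase Plk1 (1.89 ± 0.21) were both higher. The cell cycle arrest list had a median of 0.60 (adjusted p = 0.00119, and adjusted p = 0.0938 with an estimated correlation). The proliferation list had a median of 0.30 (adjusted p = 0.00168, and adjusted p = 0.42 with an estimated correlation). Cdk6, in contrast, was lower (-2.02 ± 0.19). Genes of Nodal, activin, TGF-beta and BMP signalling rose in 10 of 28 and fell in 1 (the same adjusted over the list alone), Inha and Inhbb, which Sertoli cells make, among those that rose. Nodal (chromosome 10, 60880720 to 60888085) stood at 42.6 ± 9.49 against 9.72 ± 3.22 RPKM (2.04 ± 0.18) and Lefty2 (chromosome 1, 182823250 to 182829233) at 204 ± 45.1 against 32.5 ± 10.7 RPKM (2.65 ± 0.24). The Nodal and BMP list had a median of 0.38 (adjusted p = 0.00267, and adjusted p = 0.18 with an estimated correlation). Naive and shared pluripotency genes rose in 12 of 29 and fell in 2 (12 and 3 adjusted over the list alone). The naive and shared pluripotency list had a median of 0.42 (adjusted p = 0.00699, and adjusted p = 0.342 with an estimated correlation).

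Among chromatin regulators at E14.5, histone demethylase genes fell in 7 of 22 members and rose in 0 (9 and 0 adjusted over the list alone). The histone demethylase list had a median of -0.36 (adjusted p = 0.0126, and adjusted p = 0.304 with an estimated correlation). Kdm3a (chromosome 6, 71538964 to 71582911) stood at 15.9 ± 0.544 RPKM against 41.1 ± 11.3 in wild type (-1.28 ± 0.22). The histone methyltransferase gene Ezh1 (chromosome 11, 101052429 to 101087764) stood at 9.56 ± 1.58 against 27 ± 3.87 RPKM (-1.41 ± 0.16), although neither its list (4 higher and 7 lower of 31, adjusted p = 0.307) nor that of Polycomb complexes (6 higher and 7 lower of 31, adjusted p = 0.341) passed. Dnmt3a, which establishes DNA methylation in male germ cells, was lower as well (-1.04 ± 0.22). With the Sertoli score as a covariate Dnmt3a was no longer called (-0.955 ± 0.334, limma adjusted p = 0.057).

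Sertoli cell markers rose in 23 of 25 members at E14.5, and the remaining called member, Dmrt1, which germ cells also express, fell (23 and 1 adjusted over the list alone). The Sertoli cell list had a median of 2.57 (adjusted p = 1.94e-08, and adjusted p = 0.304 with an estimated correlation). The mean log2 level over that list was 3.95 ± 0.864 in mutant libraries and 1.69 ± 0.441 in wild type, and highest in mutant library 2 (5.08). Leydig cell genes rose in 7 of 11 members and endothelial genes in 5 of 12, with 0 falling in either (the same adjusted over the list alone). The Leydig members that rose include Inha and Nr5a1, which Sertoli cells also express. The Leydig cell list had a median of 1.27 (adjusted p = 0.00168, and adjusted p = 0.254 with an estimated correlation). The endothelial list had a median of 0.80 (adjusted p = 0.00294, and adjusted p = 0.0498 with an estimated correlation). In all, 4721 genes passed at E14.5, 2351 higher and 2370 lower, 1106 and 554 of them by at least 2-fold. The count was 1807 with the Sertoli score as a covariate, a setting chosen after the data were seen, and the Sertoli list then lost its call by construction (adjusted p = 0.901), as did Clu (log2 fold change 1.48), Amh (0.16) and Inha (0.75). Among the 18 male germ cell differentiation genes called lower, the median log2 fold change went from -1.85 to -1.71 with the covariate. Their median SE rose from 0.244 to 0.36, so a lost call need not be a smaller effect. Of the 16 lists called at E14.5, 9 kept their call with that covariate at the preset correlation: male germ cell differentiation (adjusted p = 1.29e-06), piRNA (3.04e-07), methylation-sensitive germline (0.00387), p53 (3.04e-07), cell cycle arrest (0.0024), proliferation (0.0108), Nodal and BMP (0.00986), naive and shared pluripotency (0.000697) and endothelial (0.00986). Beside the Sertoli list, those of Leydig cells (0.0907), general germ cell identity (0.0851), histone demethylases (0.0728), primed pluripotency (0.0992), immediate early genes (0.0851) and the stress and unfolded protein response (0.365) lost theirs. Without the covariate only the p53 and endothelial lists were called at an estimated correlation. Several of these lists share members, so their calls are not separate results. Asz1, Mael, Mov10l1, Piwil2 and Fkbp6 belong to the male germ cell differentiation, piRNA and methylation-sensitive germline lists alike. Cdkn1a, Ccng1, Btg2 and Gadd45a belong to both the p53 and the cell cycle arrest lists.

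**Figure D2:**
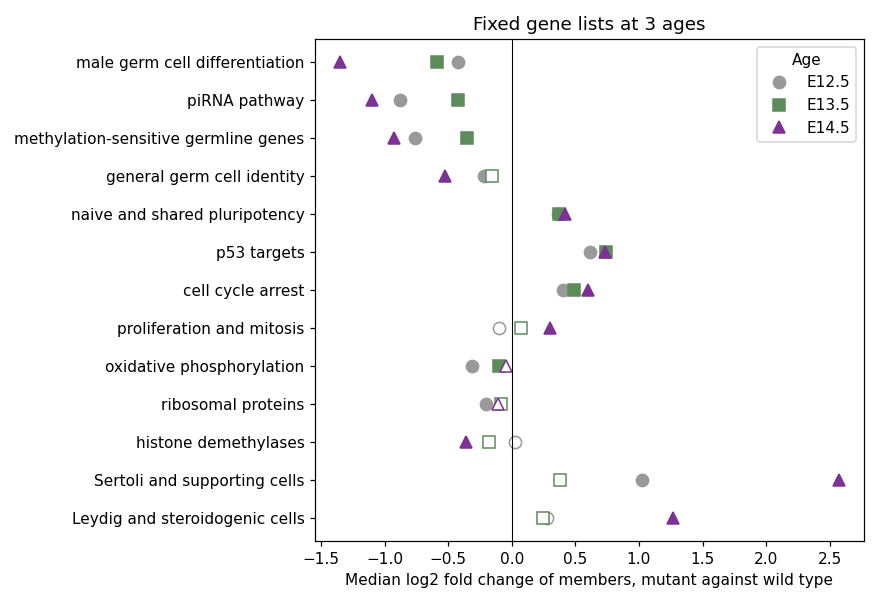
Median log2 fold change of 13 of the 37 fixed gene lists in the mutant against wild type at each age. A filled symbol marks a list whose camera test with the preset correlation gave an adjusted p under 0.05. Most of these calls were lost with an estimated correlation.

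**Figure D3:**
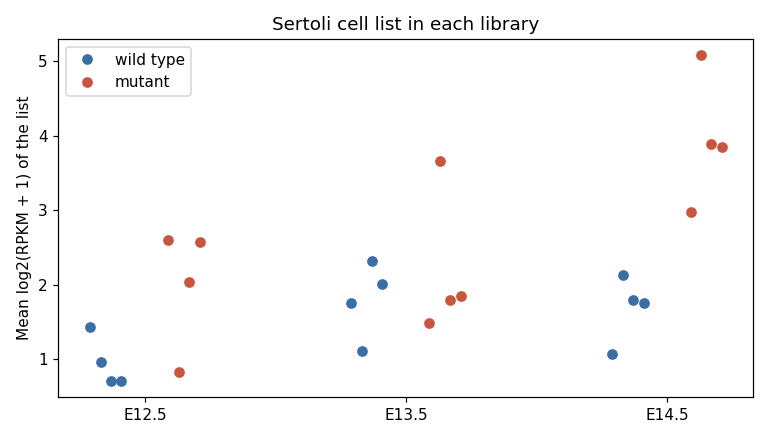
Mean log2(RPKM + 1) of all Sertoli list genes with deposited values, tested or not, in each library, by age and genotype. Each point is 1 library.

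Across the 3 ages, camera with the preset correlation called 44 tests of gene lists of 108. With an estimated correlation 3 of them held: the p53 targets at E13.5 and E14.5 and the endothelial genes at E14.5. The genes called at different ages overlapped beyond independent lists. At E12.5 and E13.5 290 genes were higher at both ages against 53.7 for independent lists, and 254 lower against 54.8. At E13.5 and E14.5 732 were higher against 177, and 502 lower against 122. At E12.5 and E14.5 375 were higher against 132, and 494 lower against 199. Genes called higher at the earlier age and lower at the later numbered 4, 0 and 22 over these 3 pairs of ages. Those called lower and then higher numbered 7, 2 and 48. All 3 ages called 238 genes higher and 213 lower.

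The mutant effect itself differed between ages for some genes. From E12.5 to E13.5 it differed for 71 genes, 47 with a more positive and 24 with a more negative effect, from E13.5 to E14.5 for 192 (88 and 104), and from E12.5 to E14.5 for 1571 (905 and 666). Nanos2, close to 0 RPKM in both genotypes at E12.5 and listed at 0 in every mutant library there, had a change of effect of -3.35 ± 0.47 to E13.5 (adjusted p = 0.00122). The change from E13.5 to E14.5 was largest on the negative side for Rrad (-3.77 ± 0.65, adjusted p = 0.00898), and Morc1 had -2.37 ± 0.42. Ak1 had 3.37 ± 0.54 from E12.5 to E14.5 (adjusted p = 0.000718), as its level in wild type dropped from 55.7 ± 7.44 to 1.19 ± 0.379 RPKM and that in the mutant went from 103 ± 11.4 to 44.9 ± 23.3 RPKM. With the Sertoli score as a covariate, chosen after the data were seen, the second count was 6 and the third 857, and of the 8 genes named from E13.5 to E14.5 only Abcd2 stayed called (-2.11 ± 0.34). Rrad (-3.90 ± 0.79) and Morc1 (-2.42 ± 0.51) were no longer called as their SE rose (adjusted p = 0.0762 for each), whereas Hsd17b3 went from 2.82 ± 0.70 to 1.04 ± 0.44, Mybpc3 from 3.17 ± 0.65 to 1.73 ± 0.53 and Wfdc10 from 3.20 ± 0.68 to 2.04 ± 0.66. The first 2 counts rest on single libraries. The first was 11 without wild type E13.5 library 2 and 407 without mutant E13.5 library 4, and the second 46 without wild type E14.5 library 1 and 544 without mutant E13.5 library 4. The third was 977 without wild type E14.5 library 1. With libraries rescaled to equal sums, the first count was 25, of which 52% were more positive in place of 66.2%, and for the third 45.4% were, in place of 57.6%.

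In wild type cells the step from E12.5 to E13.5 raised Nanos2 (4.26 ± 0.32), Egr4 (4.36 ± 0.56) and Krt17 (4.56 ± 0.39) and lowered Rhox6 (-4.22 ± 0.51), Rhox9 (-4.03 ± 0.47) and Plcd1 (-3.50 ± 0.46). Chromatin remodelling genes rose in 20 of 35 members and fell in 1 (20 and 2 adjusted over the list alone), Wnt signalling genes rose in 13 of 26 and fell in 2 (the same adjusted over the list alone) and retinoic acid signalling genes in 7 of 14 with 1 falling (the same adjusted over the list alone). The chromatin remodelling list had a median of 0.67 (adjusted p = 2.23e-06, and adjusted p = 0.0988 with an estimated correlation). The Wnt signalling list had a median of 0.67 (adjusted p = 0.000127, and adjusted p = 0.081 with an estimated correlation). The retinoic acid signalling list had a median of 0.84 (adjusted p = 0.00636, and adjusted p = 0.285 with an estimated correlation). From E13.5 to E14.5 all 19 tested piRNA pathway genes rose (19 adjusted over the list alone) and male germ cell differentiation genes rose in 20 of 24 with 1 falling (the same adjusted over the list alone), led by Rrad (4.27 ± 0.46), Nxf2 (4.08 ± 0.62) and Morc1 (3.24 ± 0.30) over all genes. The piRNA list had a median of 1.39 (adjusted p = 1.07e-08, and adjusted p = 0.201 with an estimated correlation). The male differentiation list had a median of 1.46 (adjusted p = 3.28e-06, and adjusted p = 0.264 with an estimated correlation). Ribosomal protein genes fell in 25 of 38 and rose in 1 (the same adjusted over the list alone), and Lars2 and Ybx3 had the largest falls (-3.61 ± 0.30 and -3.54 ± 0.22). Lars2 and Ybx3 stood highest at E13.5 in both genotypes, Lars2 at 1030, 6050 and 480 RPKM over the 3 ages in wild type and 1270, 7540 and 656 in the mutant. The ribosomal list had a median of -0.39 (adjusted p = 2.06e-07, and adjusted p = 0.537 with an estimated correlation). Wild type cells changed in 4692 genes at the first step (1982 up, 2710 down) and 5541 at the second (3539 up, 2002 down). Both steps involve the E13.5 libraries, and a possible batch of these cannot be told apart from a change with age. In wild type 804 genes peaked at E13.5 and 1237 dipped there. At the first step 42.2% of the called genes rose, but 50.6% with libraries rescaled to equal sums and 48.3% quantile normalized, so an excess of falls depends on the scaling.

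Mutant cells changed in 2106 genes at the first step (1116 up, 990 down) and 3993 at the second (2500 up, 1493 down). Here 455 genes peaked at E13.5 and 369 dipped there, with the same open point of a batch. The first step raised, among others, Hesx1 (3.13 ± 0.30), Sp5 (2.97 ± 0.39) and Fgf8 (2.88 ± 0.40), genes of early embryonic patterning. These genes were not tested as a group. At the second step piRNA pathway genes rose in 11 of 19 with 0 falling (the same adjusted over the list alone), Sertoli cell markers in 20 of 25 with 0 falling (22 and 0 adjusted over the list alone), and ribosomal protein genes fell in 24 of 38 (29 adjusted over the list alone). The piRNA list had a median of 0.67 (adjusted p = 0.000887, and adjusted p = 0.446 with an estimated correlation). The Sertoli cell list had a median of 1.98 (adjusted p = 6.88e-06, and adjusted p = 0.534 with an estimated correlation). The ribosomal list had a median of -0.43 (adjusted p = 2.45e-12, and adjusted p = 0.446 with an estimated correlation). The first mutant step called 1318 genes without mutant E13.5 library 4 and 1390 without mutant E12.5 library 3, and the second 2633 without mutant E13.5 library 4. With settings chosen after the data were seen, the second called 1111 with the Sertoli score as a covariate and 1659 without 3 libraries that stood apart. At the first mutant step 53% of the called genes rose, and 62% when rescaled. The second step moved the median of all genes by 0.14 in wild type and 0.15 in the mutant, and rescaling to equal sums added 0.16 and 0.13 to it where quantile normalization took it to 0.03 and 0.01. The share of called genes that rose went with it, from 63.9% in wild type to 75.7% rescaled and 51.8% quantile normalized, and from 62.6% in the mutant to 75.6% and 45.9%.

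Genes that changed with age in wild type tended to differ in the mutant at the later age in the opposite sense. Across 12669 genes, which are not independent replicates, the wild type step from E13.5 to E14.5 and the mutant effect at E14.5 had a Pearson correlation of -0.387 and a Spearman correlation of -0.432, with wild type libraries 1 and 2 of the later age used for the step and 3 and 4 for the effect. For E12.5 to E13.5 these were -0.227 and -0.169. Over the 6 ways of halving those libraries Pearson correlations ran from -0.397 to -0.312 and from -0.309 to -0.203. Without the halving the shared libraries alone give -0.5 in data simulated with no effect, and the covariances of -0.291 and -0.194 compare with -0.0715 there.

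Binding of DND1 was measured in HEK293, a human embryonic kidney cell line, by a digestion-optimized RNA immunoprecipitation (RIP) of FLAG-tagged DND1 with 2 RIP and 2 input libraries. The deposited table holds counts of binding sites per gene called by the authors, so no test of RIP against input could be made. The 2 replicates shared 28036 sites in 6300 genes, 46.2% of the 13630 genes listed as expressed. Of the shared sites 59.5% lay in 3' untranslated regions and 60.6% held the motif DAUBAW (D: A, G or U; B: C, G or U; W: A or U). Sites of either replicate numbered 93774, of which 29.9% were shared. The most shared sites were listed for HMGN2P46 (81), a name given to a pseudogene, whose reads could belong to its parent gene, followed by the nuclear import receptor gene TNPO1 (35), U2SURP (32), CLTC, the clathrin heavy chain gene (31), HNRNPU and TROVE2 (30 each), USP9X and XPO1 (29 each), and PRKDC and STAG2 (28 each).

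Shared sites were found in 48.2% of the expressed genes that had a mouse gene of the same symbol. They were more frequent in genes of oxidative phosphorylation (32 of 38; Fisher's exact test, adjusted p = 0.000188; ATP5C1 8 sites, ATP5B 6), of deadenylation and RNA decay (25 of 30, adjusted p = 0.0025; CNOT1 15, DCP2 13), ribosomal proteins (28 of 38, adjusted p = 0.0157; RPL5 12, RPS24 11), chromatin remodelling (25 of 34, adjusted p = 0.023; SMARCAD1 17, SMARCA5 15) and cell cycle arrest (17 of 22, adjusted p = 0.0397; CCNG1 8, RB1 8), and in the housekeeping reference (16 of 20, adjusted p = 0.0345). They were fewer in genes of general germ cell identity (0 of 11, adjusted p = 0.0125) and Sertoli cells (1 of 12, adjusted p = 0.0345). p53 targets did not differ from the rest (10 of 20, adjusted p = 1). This test was added after the data were seen, and longer or more abundant transcripts can hold more sites.

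Of 9171 genes tested in germ cells and expressed in HEK293, 5130 had a shared site. At E12.5 their median log2 fold change in the mutant was -0.09 against 0.06 for the other 4041, below all 10000 random lists matched on expression (95% of them -0.07 to -0.05). Of these genes 631 (12.3%) were called lower, against 5.35% of the others (odds ratio 2.48, Fisher's exact p = 1.54e-31), and 3.88% higher against 7.25%. Camera with the preset correlation gave an adjusted p = 0.00045, but adjusted p = 0.287 with an estimated correlation. At E13.5 both shares were smaller among genes with sites (4.13% against 6.24% lower, 5.63% against 9.26% higher), and the medians were 0.00 and 0.02 (percentile 65.6 of the random lists, camera adjusted p = 0.549). At E14.5 21.5% were lower against 18.9% (odds ratio 1.17, exact p = 0.00243) and 16.3% higher against 21.4%, with medians of -0.06 and 0.02 (percentile 4.22 of the random lists, within their central 95%, camera adjusted p = 0.298). Fisher's exact test and the random lists treat genes as independent, which they are not, so their small p-values and percentiles overstate the evidence. At E12.5 the share of called genes that were higher depended on scaling (40.1%, and 51.3% rescaled to equal sums). The tests of genes with sites were not repeated with rescaled or quantile normalized values. Genes were matched between species by symbol alone, and binding was measured in cells of another tissue and species.

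**Figure D4:**
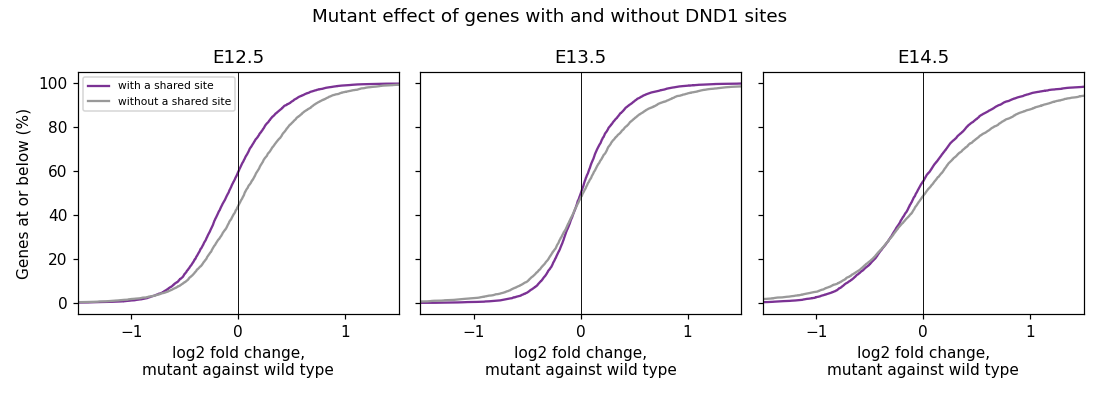
Cumulative distribution of the log2 fold change in the mutant at each age, for 5130 genes with a DND1 site shared by both HEK293 replicates and 4041 genes expressed there without one. The axis is drawn from -1.5 to 1.5.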

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

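The tests of Sertoli cells carried through the sort, of Sertoli genes transcribed in germ cells, of the close pair of libraries and of a shared batch were chosen after the results were seen, and the Sertoli covariate was a setting added after the data were seen.

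Sertoli cell markers were far higher in mutant libraries at E14.5, where the most abundant were Clu (289 against 10.8 RPKM), Cst9 (260 against 16.4), Ctsl (185 against 31) and Ptgds (145 against 9.23), although the sort for Oct4-driven GFP would be meant to remove Sertoli cells. Of the 25 tested members 18 reached 1 RPKM in wild type E14.5 libraries and 3 belong to another list. Sertoli cells carried through the sort may be a candidate source: within groups the list varied as 1 component with 78.7% of its variance, just above the 95th percentile of matched random lists (77.9%; their median was 30.3% and their highest 92.3%). Sertoli genes transcribed in the mutant germ cells themselves (median difference 2.57) cannot be told apart from this, since pooled cells hold no value per cell. Dilution of germ cell RNA as the whole cause of the lower male germ cell differentiation genes is argued against, since 13 of 18 such genes were still called lower with the Sertoli score as a covariate and all 18 kept a negative value, -3.77 to -0.641 (median log2 fold change -1.85 before and -1.71 after, SE 0.244 and 0.36), so that a change in the germ cells themselves stays open as a hypothesis.

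Mutant E12.5 libraries 1 and 4 were closer to each other than the other 35 pairs within groups. Of low genes, 9.38% were at 0 in only 1 of these libraries, against 18.7% to 28.8% in other pairs, which is consistent with 1 sample of RNA or complementary DNA made into 2 libraries. Whether 1 library was read 2 times was not decided. The spread of their log2 differences (scaled median absolute deviation) was larger over 100 RPKM than at 20 to 100 RPKM (0.141 against 0.118). The difference was 0.023, with a 95% interval over resampled genes of 0.012 to 0.033. Read sampling alone would give a smaller spread at the higher level, but without counts that noise could not be measured. Over 100 RPKM the closest other pair had 0.145. Litter mates of like age were not tested. The labels give libraries 1 and 4 as replicates.

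In both genotypes 364 genes peaked at E13.5 (28.9 for independent lists; 804 in wild type and 455 in the mutant), and 234 dipped there (36; 1237 and 369), with 0 in opposite directions. A bias by gene length was not decided: the deviation at E13.5 had a Spearman correlation across genes of -0.045 with genomic span in wild type and -0.014 in the mutant, but span includes introns, and no transcript length was in the tables used here. A library batch shared by the 8 E13.5 libraries and a change with age shared by both genotypes cannot be told apart, as age and batch would fall together and either could give the 364 shared genes. Lars2 was an extreme case, at 6050 RPKM in wild type and 7540 in the mutant at E13.5 against 480 and 656 at E14.5. Tgoln2 was another, at 3.58e-07 to 6.42e-05 RPKM in the 8 E13.5 libraries and at 1 RPKM or more in every other library. These E13.5 values of Tgoln2 are tiny but not 0, and how they arose was not tested. Changes into and out of E13.5 hold the open point of a batch. The comparisons between genotypes at E13.5 do not depend on it if the batch was the same for both.

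Single libraries were screened in each group but mutant E12.5, for each measure and printed gene. Of 205 such sets of 4 values, 19 had a value far from the other 3. Chance alone would give about 1 in 20 (10.2) for independent, normally distributed values. Some measures overlap and some values lie near 0, so that number is only a rough guide. Mutant E13.5 library 2 stood out for the Sertoli list (mean log2 level 3.67, the others 1.48 to 1.85), Clu (72.6 RPKM, the others 6.89 to 10.1), Inha (20.2, the others 2.34 to 4.77) and Amh (64.6, the others 3.13 to 6.66). Mutant E13.5 library 4 stood out for the erythroid list (2.32, the others 0.568 to 0.791), Egr4 (3.88 RPKM, the others 0 to 0.637), Ak1 (62.7, the others 87.7 to 91.3), Upp1 (0.279, the others 1.56 to 1.79) and Trp53 (309, the others 457 to 461). Mutant E13.5 library 3 held Rrad at 1.04 RPKM where the others were at 0. Mutant E14.5 library 2 had 12057 genes at 1 RPKM or more (the others 11375 to 11467) and wild type E13.5 library 1 had 10777 (10993 to 11028), with Ak1 at 21.8 RPKM (3.73 to 6.65). Wild type E12.5 library 1 stood out for the leukocyte list (0.924, the others 0.272 to 0.344), Hspb1 (16.8 RPKM, 5.52 to 6.39) and Clu (5.03, 1.57 to 1.83), wild type E12.5 library 4 for Nanos2 (0.866, 0 to 0.117) and Upp1 (2.65, 0.502 to 0.849), and wild type E14.5 library 3 for the leukocyte list (0.899, 0.37 to 0.438).

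A test of the difference singled out genes whose mutant effect changed between ages, given as log2 differences. From E12.5 to E13.5 these were Npw (3.26), Cda (2.94), Dapl1 (2.70), Apobec2 (2.15), Egr4 (-4.23), Nanos2 (-3.35), Snai1 (-3.02) and Aldh1a2 (-2.79). From E13.5 to E14.5 they were Wfdc10 (3.20), Mybpc3 (3.17), Dhrs3 (3.05), Hsd17b3 (2.82), Rrad (-3.77), Rhox10 (-2.39), Morc1 (-2.37) and Abcd2 (-2.28), of which only Abcd2 stayed called with the Sertoli covariate, and Wfdc10 (2.04, adjusted p = 0.215), Mybpc3 (1.73, adjusted p = 0.202), Dhrs3 (2.54, adjusted p = 0.129) and Hsd17b3 (1.04, adjusted p = 0.324) were smaller, whereas Rrad (-3.90), Rhox10 (-2.37, adjusted p = 0.0996) and Morc1 (-2.42) kept their size with a larger SE. From E12.5 to E14.5 they were Acsbg1 (3.87), Ak1 (3.37), Id2 (3.34), Cited1 (3.24), Egr4 (-4.20), Rrad (-4.11), Nanos2 (-3.78) and Krt17 (-3.55).

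Gene lists also differed by camera with the preset correlation, 8, 11 and 14 in the 3 contrasts between ages, and 0 with an estimated correlation, given here as the median log2 difference of members. From E12.5 to E13.5 these were histone demethylases (-0.257), chromatin remodelling (-0.268), DNA methylation (-0.18), retinoic acid signalling (-0.391), oxidative phosphorylation (0.185), leukocytes (-0.889), imprinted genes (-0.355) and methylation-sensitive germline genes (0.433). From E13.5 to E14.5 they were primed pluripotency (0.679), male germ cell differentiation (-0.752), general germ cell identity (-0.287), proliferation (0.313), cell cycle arrest (0.157), piRNA pathway (-0.739), Nodal and BMP signalling (0.245), immediate early genes (0.246), Sertoli cells (1.91), Leydig cells (1.03) and methylation-sensitive germline genes (-0.363). From E12.5 to E14.5 they were primed pluripotency (1.01), male germ cell differentiation (-0.719), meiotic entry (0.337), proliferation (0.378), histone demethylases (-0.498), histone acetylation (-0.285), chromatin remodelling (-0.334), piRNA pathway (-0.464), Nodal and BMP signalling (0.387), p53 targets (0.266), stress and unfolded protein response (0.386), oxidative phosphorylation (0.237), Sertoli cells (1.48) and Leydig cells (1.18).

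For the comparisons of genotype, 1 of 35 splits of the samples at each age, the real one, gave as many genes (1776 with 786 the highest other at E12.5, 1607 with 157 at E13.5, and 4721 with 271 at E14.5). Chance is not excluded by this, since 1 of 35 is the smallest share these splits allow. Splits that mix the groups also add a real difference to the spread, which lowers their counts. The same holds for the steps in wild type (1 of 35 each; 4692 with 1 and 5541 with 138) and in the mutant (1 of 35 each; 2106 with 1312 and 3993 with 461). For the differences between ages the splits decide nothing about chance, because they hold the real difference of genotype at each age, and exchanging the genotypes at 1 age adds both effects. As many genes came from 5 of 100 splits from E12.5 to E13.5 (71 with 511 the highest other), 4 of 100 from E13.5 to E14.5 (192 with 3809) and 4 of 100 from E12.5 to E14.5 (1571 with 4756). The splits with several times the real count point to this structure of the samples.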

How the results depend on the processing

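The fits without mutant E12.5 libraries 1 and 4, without 3 doubted libraries, with the Sertoli covariate and with sites of either replicate were chosen after the data were seen. So was the averaging of mutant E12.5 libraries 1 and 4 in the main fit. The fit with 24 separate libraries follows the design fixed first. Of 378 summary values under an alternative 313 stayed on their side of the threshold, or within 1.5 times for counts and 1 SD of the halvings for correlations, 64 moved, 1 was lost and 0 reversed. Of 11595 values of named genes and lists 10715 stayed on their side of the threshold, 807 were lost, 67 gained and 6 reversed. In both sets a value called in neither fit counted as staying on its side even if its direction changed. Dnd1 at E12.5, for example, went from -0.153 to 0.0289 without wild type library 1. Unless the construction shows it, the cause was not tested. Reversed with the Sertoli covariate were Cst9 (-0.379), Defb19 (-0.384), Gata4 (-0.359) and Aldh1a1 (-0.224) at E14.5, and for the change of the mutant effect the ribosomal list between E13.5 and E14.5 (adjusted p = 0.00314) and the Sertoli list between E12.5 and E14.5 (adjusted p = 0.98). With an estimated correlation the test of genes with DND1 sites at E12.5 gave p = 0.0958, and 3 list calls at the ages and 0 between ages held. The difference between E12.5 and E13.5 counted 43 genes with a pseudocount of 0.1, 44 unfiltered, 25 rescaled, 141 with array weights, 37 without trend and robust options, 131 with 24 libraries, 32 without mutant E12.5 libraries 1 and 4 and 127 without the 3 doubted libraries. That between E13.5 and E14.5 counted, in the same order where it moved, 101, 116, 122 rescaled, 336 quantile normalized, 514 with array weights, 83 with only the groups compared, 95 with the replicate block on 24 libraries (219 on these without the block), 313 without the 3 doubted libraries and 6 with the Sertoli covariate. That between E12.5 and E14.5 counted 857 with the Sertoli covariate. With only the groups compared, which leaves fewer samples to estimate the spread, E13.5 counted 1066, the first mutant step 713 and the second 2595. The first mutant step also counted 1239 with array weights, 1188 without mutant E12.5 libraries 1 and 4 and 1131 without the 3 doubted libraries, the second 1659 without those and 1111 with the Sertoli covariate, and E14.5 1807 with that covariate. The correlation of wild type step and mutant effect was -0.273 and -0.309 with replicates 2 and 4 or 1 and 4 on the side of the step from E12.5 to E13.5, and -0.334, -0.312 and -0.326 with 3 and 4, 2 and 4 or 2 and 3 for the later step. Sites of either replicate fell in 9840 genes in place of 6300. Leaving out 1 library at a time gave 1008 to 1845 genes at E12.5 (1008 without wild type library 4, 1089 without 3), 1061 to 1828 at E13.5 (1061 without wild type library 2), and 3849 to 4532 at E14.5. For the differences between ages it gave 11 to 407, 46 to 544 and 977 to 1650 (407 and 544 without mutant E13.5 library 4, 415 without wild type E14.5 library 2 for the second). It gave 3839 to 4418 and 4748 to 5246 for the wild type steps and 1318 to 2255 and 2633 to 3975 for the mutant steps (1318 and 2633 without mutant E13.5 library 4, 1390 without mutant E12.5 library 3), and 39 to 47 list calls at the ages. Without the 3 doubted libraries E12.5, E13.5 and E14.5 counted 2063, 1209 and 4402, and with the replicate block on 24 libraries 1982, 1283 and 4357, below the 2535, 1653 and 4795 of these libraries without the block. Of 28 correlations between libraries that share a number, running from -0.20 to 0.18, 1 lay above 0.1, so the numbers were not taken as pairs. Depth is unknown, so genes near 1 RPKM rest on the spread between libraries alone, and the absence of a call there does not show that a gene was unchanged.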

Other observations

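The gene lists described here were planned. Chosen after the data were seen were the setting without mutant E12.5 libraries 1 and 4 and, for the main fit, the averaging of these libraries into 1 sample.

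Some further gene groups moved with the mutation, given by the median log2 fold change of members. At E12.5 imprinted genes rose in 5 of 21 members and fell in 0 (7 and 1 adjusted over the list alone), with Impact at 1.38 ± 0.20 and Snrpn at 0.78 ± 0.19. The imprinted list had a median of 0.54 (adjusted p = 0.00138, and adjusted p = 0.221 with an estimated correlation). Immediate early genes, which respond to signals and to tissue dissociation, rose in 5 of 21 at E12.5 (7 adjusted over the list alone), in 3 at E13.5 (3 adjusted over the list alone) and in 10 with 1 falling at E14.5 (10 and 2 adjusted over the list alone). The immediate early list had a median of 0.41 at E12.5 (adjusted p = 0.00163, and adjusted p = 0.229 with an estimated correlation). At E13.5 its median was 0.40 (adjusted p = 0.0236, and adjusted p = 0.435 with an estimated correlation). At E14.5 its median was 0.62 (adjusted p = 0.00455, and adjusted p = 0.266 with an estimated correlation). Fos had a log2 fold change of 2.01 ± 0.45 at E12.5 and 3.35 ± 0.41 at E14.5. Ribosomal protein genes fell in 5 of 38 at E12.5 and rose in 0 (the same adjusted over the list alone), with Rpl5 at -0.49 ± 0.12. The ribosomal list had a median of -0.21 (adjusted p = 0.00153, and adjusted p = 0.678 with an estimated correlation). Male germ cell differentiation genes fell in 6 of 24 and rose in 2 at E12.5 (11 and 3 adjusted over the list alone), and general germ cell identity genes fell in 7 of 22 and rose in 1 (8 and 1 adjusted over the list alone), with Ddx4, the mouse Vasa gene, at -1.37 ± 0.26. The male differentiation list had a median of -0.42 (adjusted p = 0.00471, and adjusted p = 0.44 with an estimated correlation). The germ cell identity list had a median of -0.22 (adjusted p = 0.0154, and adjusted p = 0.324 with an estimated correlation). DNA methylation genes rose in 3 of 23 and fell in 1 at E12.5 (the same adjusted over the list alone), the maintenance factor gene Uhrf1 being the one that fell (-1.12 ± 0.29). The DNA methylation list had a median of 0.28 (adjusted p = 0.0168, and adjusted p = 0.101 with an estimated correlation). Without mutant libraries 1 and 4 the lists of ribosomal proteins, imprinted genes, general germ cell identity and DNA methylation lost their calls at E12.5 (adjusted p = 0.361, 0.109, 0.0568 and 0.0542).

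At E13.5 the lists of meiotic entry (3 of 23 lower), retinoic acid signalling (4 of 14 lower) and oxidative phosphorylation (4 of 38 lower) passed narrowly, with 3, 5 and 4 lower and 0, 1 and 0 higher adjusted over the list alone. The meiotic entry list had a median of -0.21 (adjusted p = 0.0427, and adjusted p = 0.492 with an estimated correlation). The retinoic acid signalling list had a median of -0.28 (adjusted p = 0.0488, and adjusted p = 0.435 with an estimated correlation). The oxidative phosphorylation list had a median of -0.10 (adjusted p = 0.047, and adjusted p = 0.702 with an estimated correlation). Aldh1a2, which makes retinoic acid, had a log2 fold change of -1.68 ± 0.35 at E13.5 and -2.08 ± 0.35 at E14.5. At E14.5 genes of primed pluripotency and early lineages rose in 5 of 15 and fell in 0 (the same adjusted over the list alone), but Gata4 and Gata6 among them are also made by cells of the gonad. The primed pluripotency list had a median of 0.59 (adjusted p = 0.028, and adjusted p = 0.18 with an estimated correlation). Stress and unfolded protein response genes rose in 5 of 20 and fell in 1 (the same adjusted over the list alone), with Calr at 0.70 ± 0.10. The unfolded protein list had a median of 0.25 (adjusted p = 0.0345, and adjusted p = 0.42 with an estimated correlation).

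The remaining lists did not pass camera at E14.5, given as members called higher and lower of those tested with the adjusted p. Germ cell and chromatin lists were meiotic entry 5 and 6 of 23 (0.624), histone acetylation 4 and 10 of 37 (0.251), chromatin remodelling 2 and 7 of 35 (0.23), DNA methylation 5 and 4 of 23 (0.685). RNA and signalling lists were deadenylation and RNA decay 5 and 8 of 35 (0.201), germ cell RNA-binding proteins 4 and 5 of 24 (0.307), Wnt signalling 6 and 6 of 26 (0.927), retinoic acid signalling 3 and 4 of 14 (0.923). Lists of cell state were apoptosis 8 and 4 of 26 (0.1), glycolysis and hypoxia 7 and 2 of 24 (0.341), oxidative phosphorylation 8 and 5 of 38 (0.923), ribosomal proteins 1 and 6 of 38 (0.139). The rest were imprinted genes 5 and 1 of 21 (0.307), the housekeeping reference 7 and 5 of 24 (0.478), stroma 0 and 2 of 6 (0.478), leukocytes 2 and 1 of 11 (0.341), erythroid cells 2 and 0 of 8 (0.341) and the female pathway 1 and 1 of 7 (0.923). Adjusted over the list alone these counts changed by at most 1 per direction, apart from stroma (0 and 0). For oxidative phosphorylation the median (-0.04) and the direction of the test differed in sign. The fry test, which asks whether members move one way on balance and sets a list against no other genes, called 13 lists at E12.5, 10 at E13.5 and 23 at E14.5.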
